A study of Mus musculus with 6 samples.

How the data were processed

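Total RNA from the livers of 3 wild type and 3 Cgref1 knockout mice was enriched for messenger RNA, reverse-transcribed, ligated to bubble adaptors, amplified and made into circular single-stranded DNA before sequencing, per the labels' protocols. The kit's strand information and the read length are not given in the sources used here. HISAT, Bowtie2, RSEM and DESeq2 were used by the authors, per the submitters' processing notes, which give no versions, order or settings. The genome build is not named in these notes. The chromosome names in the deposited table are those of GRCm38, all 15803 matched genes on chromosomes stood on the same chromosome in the GRCm38.p6 reference, and 8627 gene starts were equal, so coordinates are given as GRCm38.

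The deposited table held, per the file headers, 15953 genes, all typed as messenger RNA, with none of the mitochondrial genome. The authors deposited expected counts per gene and library, which were not normalized; 92.3% to 92.9% of the values in a library were whole numbers. They also deposited FPKM values and TPM values per library, per the file headers. Per the file headers the authors' table also gave a log2 fold change between the group means and a p-value and q-value from DESeq2; these were used only where the authors' deposited table is named. The sign of the authors' log2 fold change was checked against the counts and is knockout over wild type. The 6 columns of group means and 9 columns that compare single libraries were not used. Every library column carries the letter that the labels give its sample.

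Expected counts were rounded to whole numbers. Genes were kept by edgeR's filterByExpr (a minimum count of 10), which left 12033 genes, and libraries were scaled by TMM factors of 0.955 to 1.05. Wild type and knockout-labelled libraries were compared with edgeR 4.0.16 (R 4.3.3) by the robust quasi-likelihood test without a block, with Benjamini-Hochberg adjustment and a threshold of 0.05. The biological coefficient of variation was 15.8%. CPM values use the TMM-scaled library sizes. Cgref1 fell below the filter and was fitted a further time with the gene kept. Library totals of 17627734 to 18366443 counts set the counting error. Confidence intervals are at 95%, a count of 0 allows up to 3 counts, and such floors cover counting error only.

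Before the data were examined, 48 gene lists for liver metabolism, regulation, cell types and sample quality were written, and the groups, the tests, the alternatives and the rule for named genes were fixed. Single values of some genes that this rule names are not reported here and left the counts of named genes; all genes stayed in the fits and the lists. Of these lists, 42 had at least 5 tested members, 5 had fewer and 1 had no gene in the table. Lists were compared with limma 3.58.1 by camera on voom values with a preset inter-gene correlation of 0.01; camera with an estimated correlation and fry were alternatives. KEGG pathways were taken from the deposited table and tested in the same way where they had 10 to 300 tested genes. A list of intestinal genes was written later, from 30 genes, of which 29 were in the table and 26 were below 1 CPM in at least 1 library; a first choice, 23 genes below 1 CPM in all knockout-labelled libraries, summed to 197, 28 and 443 counts in wild type and 15, 24 and 17 in knockout-labelled libraries; a list of ChREBP targets was also written later.

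The text names Cgref1, the genes past the threshold or, with fewer than 5 in a direction, the 5 genes with the smallest unadjusted p in that direction at a mean of at least 1 CPM. It also names, for each list that passed, up to 2 members with the smallest p, for other metabolic lists up to 2 members with the highest mean CPM, and members past the threshold over the list alone. Genes outside this rule are given as examples and were chosen after their values were seen.

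The alternatives were DESeq2 size factors, library totals and upper-quartile factors as scaling, no filter or a mean of at least 5 CPM, DESeq2 1.42.0, limma-voom, limma-trend on log2 of FPKM or TPM with a pseudocount of 1 or 0.1, the replicate number as a block, the removal of haemoglobin and Mup genes, a log2 fold change of at least 1, and each library left out in turn. Leaving out wild type replicates 1 and 3 together, and 2 of the scalings for the lists, were added after seeing the data.

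The steps were tested on simulated data with 3 wild type against 3 knockout-labelled libraries, drawn from the real means, library sizes and dispersions. With 200 of the genes changed and 11929 genes run, edgeR recovered 18% of the genes changed by a fold of 1.5, 58% at 2, 82% at 3 and 96% at 4, with 11 false calls. With no gene changed it made 0 calls. The Benjamini-Hochberg threshold is harder to pass where fewer genes change, so the recovered shares need not hold for the real comparison. A list shifted by -0.5 on the log2 scale was recovered by the preset camera test, which called 0 lists when none was shifted. Genes were simulated independently, so this does not test camera on lists of correlated genes.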

Results

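Gene expression was measured by RNA sequencing in 6 mouse liver samples, 3 wild type and 3 from Cgref1 knockout animals, all of the C57BL/6 strain. The labels describe the 3 samples of each group as biological replicates and name hepatocytes as the cell type, while the series design speaks of liver tissue. Nothing more is said about how the replicates were obtained, so each p-value measures the spread between these samples. Library totals were 18185837, 17941830 and 17627734 estimated counts in wild type replicates 1, 2 and 3. They were 17649817, 18019408 and 18366443 in knockout-labelled replicates 1, 2 and 3. Between 14260 and 14628 of the 15953 genes in the table had a count above 0 in a library, and Alb, the gene for serum albumin, took the largest share, 5.01% to 8.04%.

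The comparison asked how hepatic gene expression differed between wild type and Cgref1 knockout mice. Cgref1, which encodes a secreted EF-hand protein, lies on the minus strand of chromosome 5 from 30933143 to 30945480 (GRCm38). Its counts were 7, 7 and 19 in the wild type libraries and 7, 12 and 10 in the knockout-labelled libraries. The levels were 0.598 ± 0.38 CPM (SD, n = 3) in wild type and 0.552 ± 0.145 CPM (SD, n = 3) in the knockout-labelled group. The transcript was thus close to the detection limit in liver and was removed by the low-count filter. With the gene kept in the fit, the log2 fold change was -0.11 (SE 0.50), the 95% confidence interval ran from -1.23 to 1.01 and the edgeR adjusted p was 0.994. Cgref1 reads were thus still counted in each knockout-labelled library, and a loss of the transcript was not seen. The interval leaves room for a partial fall, down to a log2 fold change of -1.23, which this depth could not resolve. The position of the deletion is not given in the sources used here, and counts summed over the whole gene do not separate a spared part of the transcript from a deleted one. The genotype of each library rests on its label alone, and every direction given here is that of the knockout-labelled libraries over the wild type libraries.

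**Figure D1:**
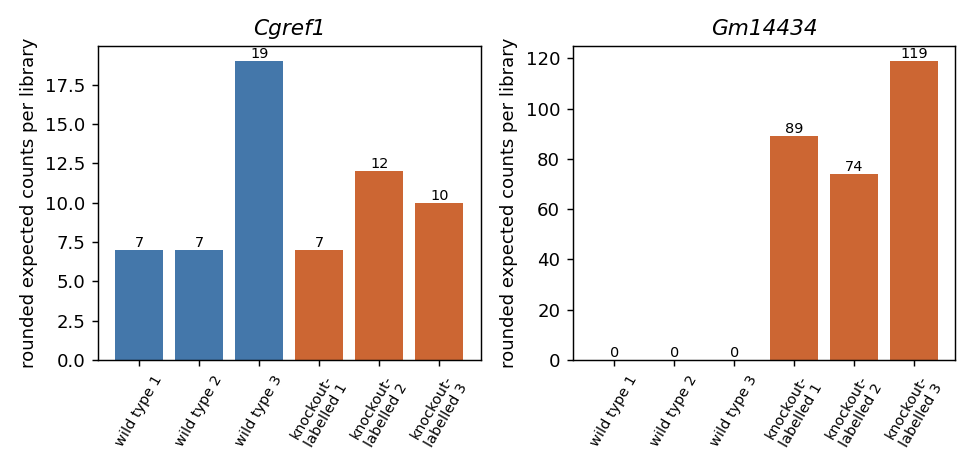
Rounded expected counts per library (vertical axes, each starting at 0) of Cgref1 and Gm14434 in the 3 wild type and the 3 knockout-labelled libraries. Cgref1 was counted 7 to 19 times in wild type and 7 to 12 times in knockout-labelled libraries, and Gm14434 was counted 0 times in each wild type library and 74 to 119 times in the knockout-labelled libraries.

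At the level of single genes, 1 of the 12033 genes tested differed between the groups. Gm14434, a predicted zinc-finger gene on chromosome 2 (176470022 to 176488246), had 0 counts in each wild type library and 89, 74 and 119 counts in the knockout-labelled libraries, or 5.35 ± 1.14 CPM (SD, n = 3). It was at least 98.5-fold higher against a floor of 3 counts over the wild type group, with an adjusted p of 0.00581 by edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment. The gene belongs to a cluster of near-identical zinc-finger genes, so the assignment of its reads is uncertain. No gene was lower past the threshold in edgeR (0 genes; 265 were lower and 355 higher at an unadjusted p under 0.05, 620 in all against 602 expected by chance). DESeq2 called 28 genes on the same counts, 16 higher and 12 lower, and limma-voom called 1. The groups did not overlap in 10.8% of the genes tested, against 10% given by chance for 3 against 3 libraries.

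The genes with the smallest p-values after Gm14434 included 4 higher ones, none of which passed the adjusted edgeR threshold. Tcta, on chromosome 9 (108302695 to 108306159), stood at 7.21 ± 0.618 CPM in wild type and 14.5 ± 0.962 CPM in knockout-labelled libraries (SD, n = 3), a log2 fold change of 1.01 with SE 0.13 and an edgeR adjusted p of 0.151. Igfbp2, which encodes a binding protein for insulin-like growth factors secreted by hepatocytes, stood at 337.3 ± 18.4 and 539.4 ± 69.8 CPM (log2 fold change 0.68, SE 0.12). Derl3, a component of endoplasmic reticulum-associated degradation, had a log2 fold change of 1.64 (SE 0.29). Gstp2 had a log2 fold change of 1.11 (SE 0.20) and shares much of its sequence with Gstp1, so its value is uncertain. Among the genes with lower values, Acacb, Acaca and Scd1 encode enzymes of fatty acid synthesis and its regulation and are given with their list. The others were the receptor tyrosine kinase gene Ntrk2, at 2.50 ± 1.07 and 0.327 ± 0.272 CPM (log2 fold change -2.92, SE 0.52), and the GABA receptor gene Gabbr2, at 16.4 ± 1.03 and 9.92 ± 1.81 CPM (log2 fold change -0.72, SE 0.15). The edgeR adjusted p of these genes lay between 0.341 and 0.646. Within 1 Mb of Cgref1, 36 of 43 genes were tested and edgeR called 0 of them, with 3 at an unadjusted p under 0.05 (Tmem214, Preb and Khk, chosen after their values were seen). Khk, the adjacent gene for ketohexokinase, had a log2 fold change of -0.34 (SE 0.11).

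Of 42 gene lists with at least 5 tested members, 12 differed by camera with a preset correlation, 8 higher and 4 lower in the knockout-labelled libraries. Camera with the correlation estimated from these samples called 0 of them (smallest adjusted p 0.213), and fry, which tests whether a list's genes move one way on balance, called 0 (smallest adjusted p 0.0548). The preset and the estimated test compare a list with all other genes, whereas fry does not. Among the 12 lists the estimated correlation ran from 0.0195 (pericentral genes) to 0.47 (major urinary proteins), against the preset 0.01. Where the estimated and preset values were close, the loss of a call need not rest on the correlation alone. The cause of these losses was not tested. At an unadjusted p under 0.05 the estimated test gave 6 lists and fry 6. Fry's mixed test, for changes in either direction, called 3 lists, which were the Kupffer cell, pericentral and hepatokine lists. No member of any list passed the edgeR threshold over all genes (0 members). Gm14434 is in none of the lists. Other splits of the libraries into 3 and 3 gave 8 to 19 lists by the preset camera test. The count of 12 lists therefore does not set the real groups apart.

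Genes of de novo lipogenesis, by which the liver makes fatty acids from carbohydrate, were lower as a list in the knockout-labelled libraries. Of 17 measured members 15 had negative log2 fold changes, with a median of -0.56 and an adjusted p of 2.05e-10 by camera. The call was lost with adjusted p = 0.26 with an estimated correlation, and the range over 14 alternatives was 1.47e-16 to 0.26. Adjusted over the list alone, 3 members were lower and 0 higher. Scd1, the stearoyl-CoA desaturase gene, fell from 12750 ± 2440 to 6017 ± 1530 CPM (log2 fold change -1.08, SE 0.21), Acacb from 95.9 ± 17.7 to 54.5 ± 2.49 CPM (-0.81, SE 0.13) and Acaca from 113.1 ± 9.82 to 76.9 ± 6.34 CPM (-0.56, SE 0.10; SD, n = 3 for each level). Fasn, the fatty acid synthase gene, had a log2 fold change of -1.11 (SE 0.35) in edgeR that did not pass, and Me1 one of -1.19 (SE 0.36); DESeq2 called both over all genes, with Scd1, Acacb and Acaca. The 2 members with positive values, Fads2 and Dgat2, had 0.03 (-0.08 to 0.23 without 1 library) and 0.20, the latter 0.03 and 0.32 without wild type replicates 1 and 3 in turn.

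Wild type replicates 1 and 3 also held the most counts of intestinal genes, with a trace in wild type replicate 2. A list of 26 intestinal genes, written after a few such genes had been seen, summed to 227, 70 and 532 counts in wild type replicates 1, 2 and 3 and to 64, 78 and 123 counts in the knockout-labelled libraries. Without wild type replicates 1 and 3, a setting added after seeing the data, the lipogenic median was -0.19 in place of -0.56 and its list adjusted p was 0.00398. In the same setting edgeR called 0 genes, with 279 at an unadjusted p under 0.05, and Gm14434 had an adjusted p of 0.101 (range over 15 alternatives 1.15e-09 to 0.101). Its fitted log2 fold change was 9.58 (SE 0.95) there and 9.59 (SE 0.62) with all libraries, so this call ended with a wider error and not a smaller difference; fitted values of a gene at 0 depend on the prior count.

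**Figure D2:**
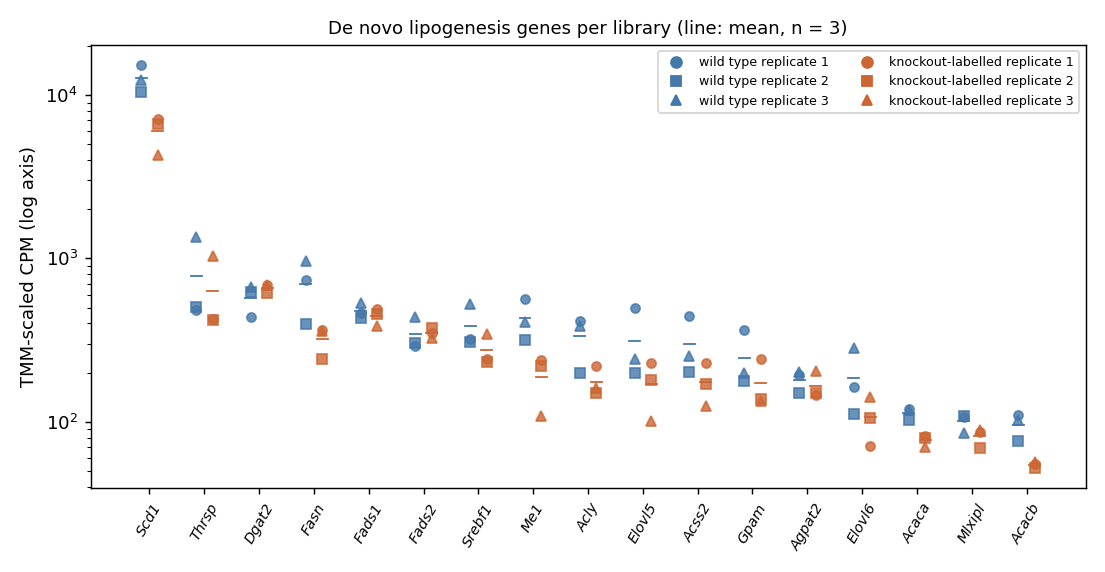
TMM-scaled CPM (vertical log axis) of the 17 de novo lipogenesis genes (horizontal axis) in the 3 wild type and the 3 knockout-labelled libraries; each point is a library and each line a group mean. Scd1 had means of 12750 and 6017 CPM, and wild type replicate 2 was the wild type library nearest to the knockout-labelled ones in Scd1, Fasn and Me1.

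Markers of Kupffer cells, the resident macrophages of the liver, were higher as a list. All 14 members had positive log2 fold changes (median 0.32, camera adjusted p 2.33e-11), with adjusted p = 0.213 with an estimated correlation (range over 14 alternatives 1.7e-11 to 0.213). Adjusted over the list alone, 6 members were higher and 0 lower: Clec4f, Csf1r, Cd5l, C1qb, Folr2 and Fcna. Clec4f rose from 48.1 ± 3.11 to 62.2 ± 0.505 CPM and the macrophage growth factor receptor gene Csf1r from 27.4 ± 1.9 to 36.1 ± 1.63 CPM (SD, n = 3). Markers of stellate cells and matrix were lower as a list, with 11 of 15 members negative and a median of -0.25 (camera adjusted p 0.0257), and adjusted p = 0.848 with an estimated correlation (range 0.000698 to 0.883). No stellate member passed in edgeR when adjusted over the list alone (0 members), among them Acta2 with 1.22 (SE 0.37; 0.73 without knockout-labelled replicate 1) and Reln with -0.28 (SE 0.11). The stellate call was lost without wild type replicate 3 (median -0.07, adjusted p 0.8), without knockout-labelled replicate 1 (-0.14, 0.187), without wild type replicates 1 and 3 together (-0.06, 0.808) and with library totals as the only scaling (adjusted p 0.102). The 15 hepatocyte markers had a median of 0.05 (adjusted p 0.267), and the 15 sinusoidal endothelial markers one of 0.03 (adjusted p 0.665).

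Pericentral hepatocyte genes, which are active around the central vein, were higher as a list. Of 16 members 14 were positive, with a median of 0.37 (camera adjusted p 8.94e-08) and adjusted p = 0.213 with an estimated correlation (range over 14 alternatives 2.35e-09 to 0.213). For this list the estimated correlation was 0.0195 and the preset one 0.01. The correlation alone may therefore not account for the lost call. Of the list's members 7 were higher and 0 lower when adjusted over the list alone: Gulo, Glul, Cyp1a2, Slc1a2, Rhbg, Slc13a3 and Oat. Glul, the glutamine synthetase gene, rose from 738.9 ± 70.9 to 1111 ± 120 CPM (log2 fold change 0.59, SE 0.12), Cyp1a2 from 658.4 ± 75.5 to 932.1 ± 93.4 CPM and the ammonium transporter gene Rhbg from 6.37 ± 1.64 to 14.3 ± 4.84 CPM (SD, n = 3). The Wnt target genes Lgr5 and Axin2 had log2 fold changes of 0.04 and 0.04 that did not pass and turned negative without 1 library (-0.15 to 0.15 and -0.09 to 0.17). The 17 periportal genes had a median of -0.11 (-0.15 to -0.02 without 1 library) and did not differ past the threshold (camera adjusted p 0.29). A difference between the zones was not tested.

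Genes of the unfolded protein response, which answers to misfolded protein in the endoplasmic reticulum, were higher as a list, with 22 of 23 members positive, a median of 0.18 (camera adjusted p 5.15e-07) and adjusted p = 0.316 with an estimated correlation (range 3.43e-10 to 0.316). Single members did not pass in edgeR when adjusted over the list alone (0 members); Sdf2l1 had a log2 fold change of 0.53 (SE 0.15) and Asns one of 1.28 (SE 0.46). Acute phase genes were higher as a list with 15 of 25 members positive (median 0.18, adjusted p 0.000415), and adjusted p = 0.26 with an estimated correlation (range 2.22e-05 to 0.26). Adjusted over the list alone, Lcn2 and Serpina3n were higher and Hamp, the hepcidin gene, was lower. Serpina3n rose from 273.7 ± 24.3 to 368.5 ± 27.5 CPM, and Hamp fell from 625.1 ± 99.6 to 386.7 ± 77 CPM (SD, n = 3). Hepatokines, proteins the liver secretes as signals, were higher as a list with 15 of 20 members positive (median 0.18, adjusted p 0.0471), and adjusted p = 0.848 with an estimated correlation (range 0.00122 to 0.848). Igfbp2 and Enho were higher and Hamp was lower when adjusted over the list alone; Enho, which encodes adropin, rose from 3.88 ± 1.13 to 12.3 ± 5.45 CPM. The median of this list was 0.06 without wild type replicate 1, and its adjusted p was 0.219, 0.173 and 0.116 without wild type replicate 1, wild type replicate 2 and knockout-labelled replicate 3.

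All 11 members of the glucocorticoid and metallothionein list were positive (median 0.33, camera adjusted p 0.000215), with adjusted p = 0.584 with an estimated correlation (range 2.05e-09 to 0.775). Of these, 1 member was higher and 0 lower when adjusted over the list alone: Lcn2, an iron-scavenging protein gene, at 2.95 ± 0.944 and 6.46 ± 1.76 CPM (SD, n = 3). The glucocorticoid target gene Zbtb16 had a log2 fold change of 1.36 (SE 0.65), and 0.92 and 2.23 without wild type replicates 1 and 2 in turn. Without wild type replicate 1, whose score of -1.05 was the lowest, the median of the list was 0.12 and its adjusted p 0.0885, and without wild type replicate 3 the median was 0.70.

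Genes that differ between the sexes in liver were tested as 3 lists. A further list, of Y-linked genes and Xist, had 4 tested members, too few for a list test. Of these 1 was positive and 3 were negative, with a median of -0.11, and Xist was not among the deposited genes. Male-biased genes were higher as a list (13 of 16 positive, median 0.32, camera adjusted p 1.69e-06), with adjusted p = 0.26 with an estimated correlation (range 1.15e-10 to 0.26). Adjusted over the list alone, 3 were higher and 0 lower: Cyp7b1, an oxysterol hydroxylase gene, from 214.6 ± 48.7 to 473.1 ± 125 CPM, Cyp2d9 from 993.4 ± 213 to 1412 ± 106 CPM and Susd4 from 47.3 ± 8.41 to 66.2 ± 6.68 CPM (SD, n = 3). Major urinary protein genes, which encode pheromone carriers, had 16 of 18 positive values and a median of 0.90 (adjusted p 5.32e-08), with adjusted p = 0.527 with an estimated correlation (range 1.33e-23 to 0.629). In edgeR 0 of them passed when adjusted over the list alone; Mup7 had 0.58 (SE 0.20) and Mup2 0.94 (SE 0.33). These genes are near-identical copies, 3 of them also stand in the male-biased list, and their single values are uncertain. Female-biased genes were lower as a list (5 of 6 negative, median -0.81, adjusted p 0.042), with adjusted p = 0.495 with an estimated correlation (range 0.000284 to 0.629). In edgeR 0 of the female-biased genes passed when adjusted over the list alone; Acot3 had -1.21 (SE 0.56) and Atp6v0d2 0.45 (SE 0.25), and without wild type replicate 3 they had -0.80 and 0.30. The scores of the male-biased list were -0.61, -0.05 and -0.40 in wild type and -0.20, 0.69 and 0.58 in knockout-labelled replicates 1, 2 and 3, so that knockout-labelled replicate 1 lay within the wild type range. The same library lay within that range in the major urinary protein list (-0.46, wild type -0.58 to -0.09) and the female-biased list (0.57, wild type 0.01 to 0.75). The female-biased call was lost without wild type replicate 3, knockout-labelled replicate 2 or knockout-labelled replicate 3 (adjusted p 0.185, 0.09 and 0.107) and with library totals or upper-quartile factors (0.216 and 0.0507). Its median was -0.43, -1.24 and -1.22 without wild type replicate 1, wild type replicate 2 and knockout-labelled replicate 1, and without wild type replicates 1 and 3 together it turned positive (0.16, adjusted p 0.559), while the male-biased median was 0.26. With no low-count filter the female-biased median was -0.34 over 15 members, and by limma-voom it was -1.39.

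**Figure D3:**
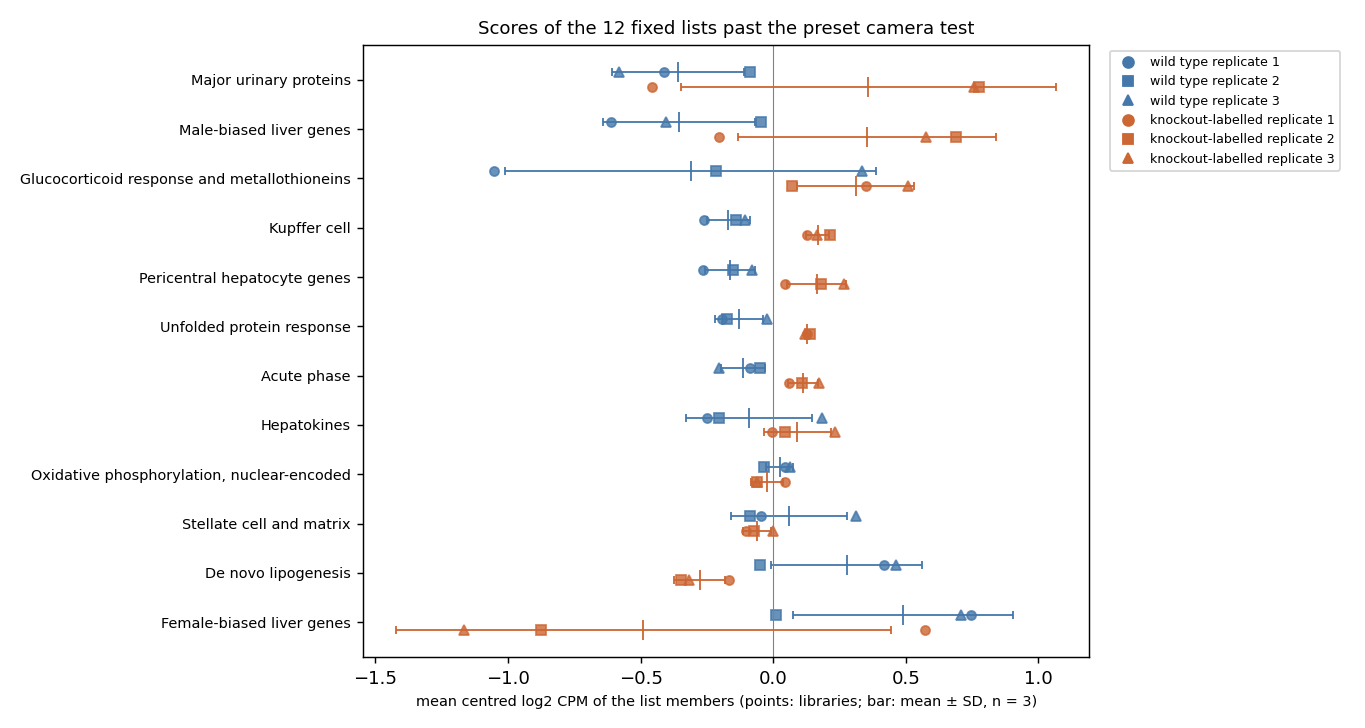
Score of each of the 12 lists that differed by the preset camera test (vertical axis) as the mean centred log2 CPM of its members (horizontal axis); points are libraries, with the group mean and SD (n = 3) as bars. The scores of 5 lists did not overlap between the groups, namely Kupffer cell, de novo lipogenesis, pericentral, unfolded protein response and acute phase. These 5 were the only such lists among all 42 tested, where chance gives 10% for 3 against 3 libraries. The 12 lists shown had been picked for differing between the same groups.

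Nuclear genes of oxidative phosphorylation were lower as a list by a small amount, with 52 of 78 members negative and a median of -0.05 (camera adjusted p 0.0309), and adjusted p = 0.859 with an estimated correlation (range 5.8e-05 to 0.883). In edgeR 0 of the 78 passed when adjusted over the list alone, among them Ndufa4 with -0.25 (SE 0.11) and Ndufa5 with -0.26 (SE 0.12; -0.16 without wild type replicate 1). Its adjusted p was 0.0689 and 0.404 without wild type replicate 1 or 3, and 0.301 and 0.156 without knockout-labelled replicate 2 or 3. Its median was -0.08, -0.02, -0.08, -0.03 and -0.03 without wild type replicate 2, wild type replicate 3 and knockout-labelled replicates 1, 2 and 3 in turn, and 0.00 without wild type replicates 1 and 3 together, where its direction in the test reversed (adjusted p 0.704); with library totals as the only scaling it was -0.13. The annotated KEGG pathway of oxidative phosphorylation had 50 positive and 61 negative genes (median -0.02, camera adjusted p 0.86). The other 30 lists tested had an adjusted p of at least 0.101 and medians from -0.18 to 0.14, and in 19 of them the median changed sign when 1 library was left out. Glycolysis genes had 14 of 18 negative values (median -0.05, camera adjusted p 0.101). Their median was -0.092 to -0.003 without 1 library. Gapdh had a log2 fold change of -0.18 (SE 0.11), and -0.10 without wild type replicate 1. Cholesterol synthesis genes had a median of -0.06 (adjusted p 0.893; -0.21 to 0.18 without 1 library), and Sc5d had -0.52 (SE 0.32), which lay between -0.76 and -0.18 without 1 library. Insulin signalling genes had a median of 0.07 (adjusted p 0.219), with 0.06 for Akt2 (0.00 to 0.11 without 1 library). Both the median (-0.01) and Akt2 were negative with library totals as the only scaling. Targets of the transcription factor CREB-H had a median of -0.08 (camera adjusted p 0.738), which was -0.144 to -0.006 without 1 library. Adjusted over the list alone, Apoa4 and Creb3l3 were higher and Apoc2 and Hamp were lower. Apoa4 rose from 48.7 ± 8.59 to 80.4 ± 17.7 CPM and Apoc2 fell from 240.3 ± 29.2 to 174.7 ± 25.9 CPM (SD, n = 3). In the bile acid list (median 0.04, adjusted p 0.549) Cyp7b1 alone passed when adjusted over the list alone. Gluconeogenesis genes had a median of -0.01, a mean of 0.08 and a higher direction in the test (adjusted p 0.731). Circadian clock genes had a median of 0.06, a mean of -0.01 and a higher direction (adjusted p 0.731). Growth hormone signalling genes had a median of -0.02, a mean of 0.06 and a higher direction (adjusted p 0.893). Fatty acid oxidation genes had a median of 0.00, a mean of -0.06 and a lower direction (adjusted p 0.738), and the urea cycle list a median of -0.01, a mean of -0.02 and a higher direction (adjusted p 0.995).

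Of the 247 annotated KEGG pathways tested, 2 differed by camera with the preset correlation, both higher. The complement and coagulation cascades, made largely by hepatocytes, had 48 positive and 26 negative genes (median 0.07, adjusted p 0.0153), and protein processing in the endoplasmic reticulum had 109 positive and 51 negative genes (median 0.07, adjusted p 0.0153). Both calls were lost, with adjusted p = 0.993 with an estimated correlation (ranges 0.000317 to 0.993 and 0.000686 to 0.993). That test and fry called 0 pathways, with 3 and 7 at an unadjusted p under 0.05. The complement call was lost without wild type replicate 3, knockout-labelled replicate 1 or knockout-labelled replicate 2 (adjusted p 0.301, 0.268 and 0.196) and without wild type replicates 1 and 3 together (0.282), and the endoplasmic reticulum call without wild type replicate 2 or knockout-labelled replicate 2 (0.106 and 0.196). The count of pathways was 0 without knockout-labelled replicate 2, 1 without wild type replicate 3, 4 without wild type replicate 1, 6 without wild type replicate 2 and 5 without knockout-labelled replicate 3.

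The authors' deposited table listed 27 genes with a q-value under 0.05, 17 higher and 10 lower. Of these 27 genes 24 were tested here, and 24 of the 28 genes called by DESeq2 here were among them. In the authors' deposited table Gm14434 had a log2 fold change of 9.06, Tcta 1.00, Enho 1.66, Cyp7b1 1.14, Scd1 -1.09 and Acacb -0.82. The authors' deposited table also listed the intestinal genes Reg3g (-6.82) and Muc13 (-6.65), which had at most 45 counts in a library and were removed here by the low-count filter. Their counts were 26, 2 and 37 for Reg3g and 11, 2 and 45 for Muc13 in the wild type libraries and 0 in each knockout-labelled library.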

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

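Leaving out wild type replicates 1 and 3 together, and the list counts with library totals or upper-quartile factors, were chosen after the results were seen. With the mean of at least 5 CPM 0 genes were called (0 higher), since this filter removes Gm14434, and it gives no value for Cgref1. DESeq2 called 28 genes (16 higher, 12 lower), and leaving out 1 library gave 1 to 5 (1 to 5 higher, 0 lower), the 5 without knockout-labelled replicate 1 being Gm14434, Mup2, Mup8, Mup9 and Mup16. Without wild type replicates 1 and 3, which leaves 1 wild type library assumed to vary like the others, 0 genes were called (0 higher), with 17 lists and 5 pathways. Camera with an estimated correlation and fry each called 0 lists and 0 pathways; lists numbered 11 to 15 and pathways 0 to 6 without 1 library. Except where the filter or fewer samples account for it, the cause was not tested.

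With the replicate block, which treats equal replicate numbers as paired, 34 genes were called (19 higher, 15 lower), with 13 lists and 2 pathways. Deviations of libraries with equal numbers correlated at 0.283, 0.06 and 0.348, not all over 0.1, so the numbers were not taken to pair the samples. Every sample correlated best with its own number, a hint from the data and not the design.

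The Cgref1 log2 fold change was reversed in limma-voom (0.024) and ranged from -0.358 to 0.534 without 1 library. Of 61 other named genes 56 kept their direction in every alternative run, and 5 reversed in at least 1. Without wild type replicates 1 and 3, 4 of these reversed, Akt2 (-0.038), Slco1b2 (0.041), Cyp3a11 (0.029) and Cps1 (0.094), and the oxidative phosphorylation list reversed with an adjusted p of 0.704. With library totals alone Akt2 was -0.027; this scaling moved the median of all genes to -0.084. Without 1 library, values ran from -0.104 to 0.046 for Slco1b2, -0.003 to 0.165 for Apoe, -0.348 to 0.005 for Cyp3a11 and -0.127 to 0.018 for Cps1. None of these genes was called in edgeR. Over all alternatives of the other named genes, 929 values kept their direction and side of the threshold, 26 passed it newly and 1 no longer passed; for the lists and pathways called, 138 stayed past it, 52 did not and 1 reversed. In the main fit Gm14434 alone of the 61 genes passed, so for the rest keeping their side of the threshold meant staying uncalled. Leaving out 1 library moved 20 of the 61 genes by over 1.5 times. Depth limits Cgref1, counted at most 19 times in a library.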

Other observations

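The tests of hepatocyte share, of all-or-none counts, of the Scd1 counts and the other lipogenic counts, of intestinal genes kept without regard to group, of both wild type libraries left out together and of ChREBP targets were chosen after the results were seen. Targets of ChREBP, the carbohydrate-responsive transcription factor, were looked at as a further group. Of 12 tested targets 11 had negative log2 fold changes (median -0.26), with an unadjusted camera p of 1.35e-06, 0.0582 with an estimated correlation and 0.0685 by fry. Pklr, the liver pyruvate kinase gene, had -0.52 (SE 0.16) and Tm6sf2 -0.48 (SE 0.15), and 2 of the targets are also in the lipogenesis list. Khk, the gene adjacent to Cgref1, is among the targets as well (-0.34, SE 0.11).

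The de novo lipogenesis list was lower in the knockout-labelled libraries by the preset camera test, with a median of -0.556. The call was lost by camera with an estimated correlation (adjusted p 0.26) and by fry (adjusted p 0.247). A lower share of hepatocytes would lower hepatocyte markers too, but their median was 0.051; the lipogenic median stayed at or below -0.523 without any 1 library and at or below -0.562 under 3 other scalings. Without both wild type libraries with the most intestinal counts, however, the median was -0.189. This was closer to 0 than 0.5 times its value, a bound that no omission of 1 library crossed. The median difference thus rests largely on these 2 libraries. The members that passed over the list alone kept more of theirs. They had been picked for small p in these same libraries, wild type replicate 2 included. That they kept more was thus partly fixed by the choice and is no separate support. Over 16 alternatives, this setting included, Scd1 stayed at or below -0.816, Acacb at or below -0.488 and Acaca at or below -0.417. With all libraries they had -1.083, -0.814 and -0.556. Wild type replicate 2 is the only wild type library left in the setting without both. An effect of the genotype and a difference in feeding or dissection between animals stay open, since neither was tested.

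Gm14434 was counted in the knockout-labelled libraries alone. Of 10 other genes of its cluster on chromosome 2 with a mean of 3 to 60 counts, 40% were all-or-none. They were at 0 in 1 library and at 20 counts or more in another. The share was 0.99% of 3631 other genes (Fisher's exact test, one-sided p 2.5e-06). All-or-none assignment of reads among near-identical genes is therefore a candidate explanation. However, each of these 4 cluster genes was at 0 in 1 knockout-labelled library alone, and the groups overlapped in all of them. None was at 0 in all 3 libraries of a group, as Gm14434 was in wild type, so this test does not address that pattern. Gm14434 gained 5.348 CPM, too little to see against the spread of the summed CPM of the other cluster genes. A shift of reads from these other genes cannot be told apart, since their summed CPM changed by -31.218 with a pooled SD of 54.17. Nor can a variant haplotype, since 4.3% of 23 other cluster genes had groups that did not overlap (upper bound 21.9%, against 10% by chance).

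Intestinal transcripts stood mainly in wild type replicates 1 and 3, with a trace in wild type replicate 2. That library held 70 counts of the list, within the knockout-labelled range. However, 13 list genes were above 0 in it, against 6 to 7 in knockout-labelled libraries. It also held 7 counts of the 4 genes seen first, against 0 in each knockout-labelled library. Leaving out wild type replicates 1 and 3 therefore need not remove all intestinal RNA. The intestinal list held 532 counts in wild type replicate 3 and 227 in wild type replicate 1 against at most 123 in a knockout-labelled library, and 25 of its 26 genes were above 0 in 1 or both of these libraries, which is consistent with carried-over intestinal tissue; its most abundant genes in wild type replicate 3 were Lypd8 (86 counts) and Zg16 (63 counts), while Tff3 was highest in knockout-labelled replicate 3 (58 counts). The marker counts argue against intestinal RNA as the supply of the higher Scd1 counts. Scd1 in wild type replicate 3 exceeded the knockout-labelled mean by 122997 counts. The intestinal genes had 649 counts there, the list's 532 and 117 of the 4 genes seen first. These markers do not measure all intestinal RNA. Fabp2, Lgals4 and Krt8 were left out, since every library held them at 1 CPM or more. Fabp2 had 2204, 1378 and 2115 counts in wild type and 1259, 1400 and 1098 in knockout-labelled replicates 1, 2 and 3. For the 14 other lower lipogenic genes such a supply cannot be told apart, since the counts gained exceeded the intestinal counts by over 10 times in both libraries for 1 of them (Fasn). Without the library with most intestinal counts the lipogenic median was -0.523, but the value of -0.189 without both libraries shows that leaving out 1 does not test what both share.

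The 6 libraries can be split into 3 and 3 in 10 ways, the real one included, too few for a share under 0.05. For genes the real value was 1 and the highest other 10, with 3 of the 10 splits, the real one counted, giving as many. The split with 10 genes, wild type replicates 1 and 2 with knockout-labelled replicate 1 against the rest, also had 1615 genes at an unadjusted p under 0.05, which points to a structure of the samples other than the groups. For lists the real value was 12 and the highest other 19, with 4 of the 10, the real one counted, giving as many. For pathways the values were 2 and 40, with 8 of the 10, the real one counted. The other splits gave 8 to 19 lists each. The preset camera test thus called about as many lists when the libraries were grouped otherwise.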
